A study of Drosophila melanogaster with 6 samples.

How the data were processed

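RNA-seq was analysed from 6 libraries of unfertilized Drosophila melanogaster eggs, 3 from mothers that overexpressed wild-type MEK in the germline and 3 from mothers that overexpressed MEK F53S. Per the labels' protocols, eggs were collected over a window of 0 to 30 min, kept in RNA-later, homogenised in TriReagent and purified on a Zymo column, and directional Illumina libraries were made. Whether RNA was selected by its poly(A) tail is not given in the sources used here. Per the submitters' processing notes, the authors quantified the reads with Salmon 0.8.2 and name the genome build dm6. The transcript annotation, the strand setting and the bias options of Salmon are not given in the sources used here.

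Per the file headers, each library has 1 deposited table with a length, an effective length, a TPM value and an estimated count for each gene. The estimated counts deposited by the authors are read numbers that need not be whole, and they are not normalised for depth. The TPM values deposited by the authors are scaled for transcript length and to a fixed total per library. The other deposited column used, the effective length, is in bases and differs between libraries for the same gene, per the file headers. All tables list the same 13943 features, of which 13831 were matched to a gene symbol and 112 were not. Gene positions were taken from a reference annotation of the same dm6 assembly. Reads that Salmon splits between near-identical gene copies, such as histone, Hsp70 and Sdic genes, leave the values of single copies uncertain, and so do overlapping genes. Exons of Hsp22, Kr-h1 and inaF-D are shared for 100%, 78.6% and 84.1% of their length with another gene on the same strand, and those of Cys and fuss for 90.7% and 30.4% with a gene on the other strand.

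Estimated counts were rounded to whole numbers. Libraries held between 37224814 and 48756311 estimated counts. Genes were filtered with the filterByExpr function of edgeR (minimum count 10, minimum total 15), which left 7539 genes and at least 99.9% of the counts in every library. Counts were scaled with TMM factors, and groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with no covariate. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. Fold changes are log2 of MEK F53S over wild-type MEK, with the standard error (SE) derived from the quasi-likelihood F statistic, and levels are TMM-normalised CPM given as mean ± SD. A gene with no count in a group was set at a floor of 3 counts per library, which is 0.0567 to 0.0881 CPM. Floors cover counting error only, because reads copied by PCR are not independent molecules.

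Before the data were examined, 23 gene lists and the rule for named genes were fixed. The rule takes Dsor1 and the markers of genetic background, the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean of at least 5 CPM and groups that do not overlap, the 5 with the smallest p in each direction, and up to 4 members of each list with the smallest p. Other genes named were called list members, or were chosen after their values were seen, as stated there. Of the list members, 643 were matched and 16 symbols were not. Lists with at least 3 tested genes, 19 in all, were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Calls were counted per chromosome arm with Fisher's exact test, two-sided. Library properties were compared with exact permutation tests, two-sided, which cannot go below p = 0.1 with 3 samples against 3.

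The test was tested on simulated data with the means, spreads and depths of these libraries in 5 draws. It recovered 65.5% of the genes changed 2-fold and 23.7% of those changed 1.5-fold, and 5.87% of its calls were false. Over all 5 draws, 484 tested genes were changed 2-fold and 489 were changed 1.5-fold. Each draw thus changed a far smaller share of genes than the 1900 of 7539 called in the data. Because the adjustment of p depends on that share, these rates may not carry over. All 5 planted lists were called by camera and 0 of 110 random lists were. Each planted list held only genes raised 2-fold, so its call does not measure power for lists with smaller or mixed changes. Genes were drawn independently of each other, so these rates do not check the preset correlation of camera where genes vary together. Replicates within a group differed beyond sampling noise, with a chi-square per degree of freedom of at least 29.4, so no library was counted as a repeat of another. Alternatives covered other scalings, count filters, dispersion estimates, an effective length offset, the replicate number as a block, DESeq2 1.42.0, limma on log2(TPM + 1), and leaving out each library. Alternatives added after seeing the data left out the mitochondrially encoded genes or removed a trend with gene length. No genome sequence was used, so GC content was not checked.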

Results

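The series measured the maternal transcriptome of Drosophila eggs laid by females with either of 2 transgenes. MEK is the kinase that activates the MAP kinase ERK, and Dsor1 is its gene in the fly. The F53S change is a gain-of-function change of the kind found in RASopathies, developmental disorders of the RAS and ERK pathway. Both transgenes were driven in the female germline by MTD-GAL4, a combination of GAL4 drivers active through oogenesis, fathers were sterile, and the labels call the eggs unfertilized. Each group had 3 libraries, described by the submitters as biological replicates. Total estimated counts ranged from 37342085 to 48756311 in wild-type MEK libraries and from 37224814 to 48485330 in MEK F53S libraries. The question was which maternal transcripts differ when the overexpressed kinase is the activated form. The 2 groups come from 2 fly lines, so for every gene an effect of the transgene cannot be told apart from one of genetic background.

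Eggs from MEK F53S mothers had high levels of several transcripts that were scarce with wild-type MEK. Pvr, a receptor for factors related to PDGF and VEGF (2L, 8220980 to 8239878 in dm6), stood at 1.23 ± 0.117 CPM with wild-type MEK and at 119 ± 15.04 CPM with MEK F53S (log2 fold change 6.59 ± 0.19 SE, adjusted p = 1.07e-07, n = 3 per group). The targets of ERK signalling pnt and aos rose by 3.53 and 3.25 on the log2 scale. In the other direction, bcd, the transcript of the anterior determinant Bicoid (3R, 6755842 to 6759466), fell from 899 ± 51.3 to 256 ± 27.9 CPM (log2 fold change -1.81 ± 0.12 SE, adjusted p = 1.65e-05). In all, 1900 of 7539 genes tested were called, 930 higher and 970 lower in MEK F53S, and rises were larger: 382 higher and 157 lower calls were at least 2-fold.

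Dsor1 itself did not differ detectably between the groups. Its level was 1370 ± 182 CPM with wild-type MEK and 1336 ± 229 CPM with MEK F53S (log2 fold change -0.04 ± 0.14 SE, adjusted p = 0.88), at X, 9247342 to 9250037 in dm6. The counts do not separate the gene of the fly from a transgene of the same sequence, so they do not check the label of each library. The eye colour gene w, a common marker on transgenes, fell from 1710 ± 116 to 965 ± 174 CPM (log2 fold change -0.83, adjusted p = 0.00231). The background markers bw, y and cn averaged under 3 CPM in both groups and were not called, v and ry had 0 counts in every library, and sc had 0 counts with wild-type MEK and 40 in total with MEK F53S.

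**Figure D1:**
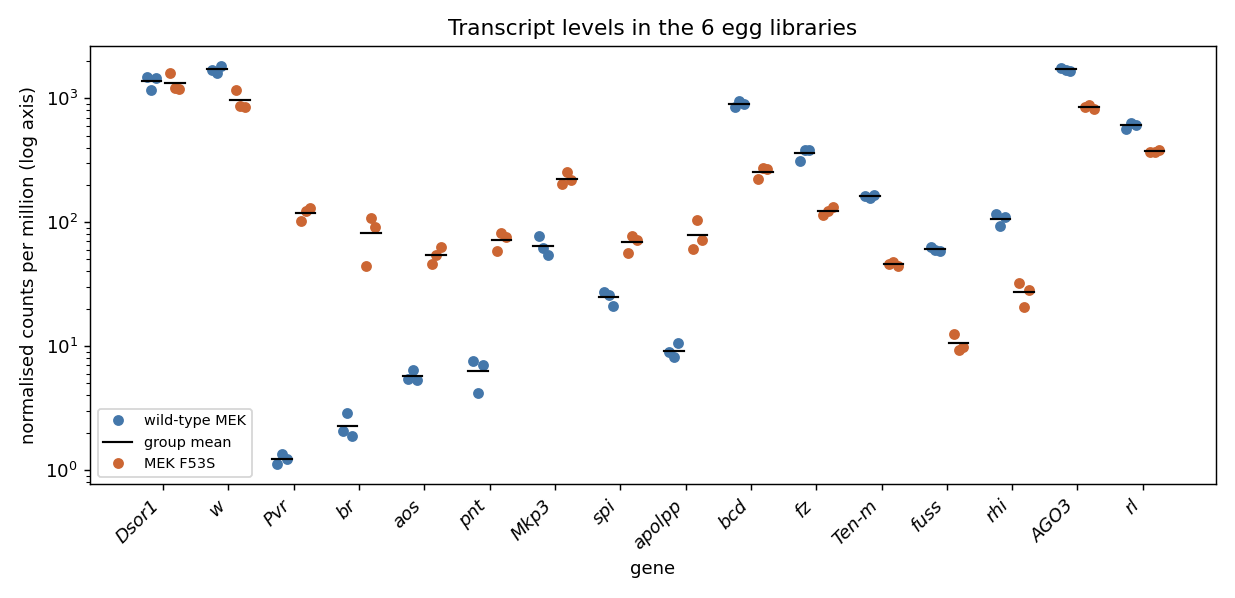
Normalised CPM (log axis) of 16 genes in each of the 6 libraries, with wild-type MEK in blue, MEK F53S in orange and a bar at each group mean of 3 libraries. Dsor1 overlaps between the groups, whereas Pvr lies at 1.23 CPM on average with wild-type MEK and 119 CPM with MEK F53S, and bcd at 899 and 256 CPM.

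Among the 10 largest rises of genes with a mean of at least 5 CPM, Nepl19, a gene of the neprilysin-like protease family, had 0 counts in all wild-type MEK libraries and 17.7 ± 3.63 CPM with MEK F53S, at least 223-fold higher (floor of 3 counts per library). Kr-h1, a zinc finger transcription factor of hormone responses, rose from 0.233 ± 0.139 to 77.6 ± 15.7 CPM (log2 fold change 8.40), though CG45075 shares most of its exons, and br, an ecdysone-induced transcription factor, from 2.27 ± 0.536 to 81.3 ± 33.0 CPM (log2 fold change 5.17). Prosalpha1R, a relative of a proteasome subunit gene, rose by 9.53 on the log2 scale, with levels spread between 11.98 and 60.2 CPM in MEK F53S. Whether its reads are shared with that related gene was not checked, so its value is uncertain. The log2 fold changes of bark, which acts at cell junctions, and of Cys, a protease inhibitor, were 6.68 and 5.58, the second uncertain because a gene on the other strand overlaps it. FBgn0003328 and FBgn0259697, which the name table does not pair with a symbol, rose by 6.06 and 4.81. Sdic3 (log2 fold change 6.88) belongs to a family of near-identical copies and its value is uncertain. The smallest p-values among rises also included Slc45-1, CG31431, Cyp6d4 and CG3961, with log2 fold changes of 4.19, 2.92, 2.54 and 2.22.

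Among genes with a mean of at least 5 CPM, the largest falls included those of CG4570, CG7720 and CG10738. CG4570 fell from 190 ± 3.56 to 9.84 ± 3.22 CPM (log2 fold change -4.28, adjusted p = 9.76e-06), and CG7720 and CG10738 fell by 4.49 and 3.91 on the log2 scale. The transcription factor gene trh and fuss, a gene of the Ski and Sno family on chromosome 4, had log2 fold changes of -2.48 and -2.52. CG3036, CG13101, dpr6 and Asph fell by 2.90, 2.77, 2.58 and 2.56. A single histone copy, His2B:CG33882, was also among them (log2 fold change -4.35), but histone copies share reads and its value is uncertain. Among abundant transcripts, fz, the receptor of planar cell polarity and Wnt signals, fell from 359 ± 39.98 to 123 ± 8.29 CPM, and Ten-m, a teneurin, from 162 ± 4.80 to 45.98 ± 1.88 CPM. HIP and Kpc1 had log2 fold changes of -1.94 and -2.02.

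Of 12 tested ERK-responsive genes, 6 rose, 2 fell and 4 did not pass the test. Besides pnt and aos, the ERK phosphatase gene Mkp3 rose from 64.7 ± 11.5 to 225 ± 25.6 CPM (log2 fold change 1.79), the EGF receptor ligand gene spi from 24.8 ± 3.19 to 68.8 ± 11.4 CPM (1.47), and kay, which encodes Fos, by 0.80. The log2 fold change of rho was 2.86, but its call was lost in 4 of the 6 fits that leave out a library, with the lowest value without MEK F53S replicate 3, where 356 of the 441 MEK F53S counts lay (log2 fold change 1.296, adjusted p = 0.416). The ligand gene vn and the phosphatase gene PTP-ER fell by 1.74 and 0.47. The counts were the same when adjusted over the list alone. As a set these genes ranked higher in MEK F53S than the other genes (camera adjusted p = 0.000459), but not with an estimated correlation (adjusted p = 0.187 with an estimated correlation). Without MEK F53S replicate 1 or 3, vn was the 1 fall that remained.

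The components of the ERK pathway moved both ways. Of 28 tested, 4 rose (pnt, Mkp3, dos and RasGAP1), 4 fell and 20 did not pass, with the same counts adjusted over the list alone. The ERK gene rl fell from 606 ± 34.8 to 373 ± 6.03 CPM (log2 fold change -0.70, adjusted p = 0.00116), and Nf1, mts and PTP-ER fell by 0.70, 0.50 and 0.47. The list was not called (camera adjusted p = 0.996), and its median of -0.09 and mean of 0.09 differ in sign. Falls numbered 2 without MEK F53S replicate 1 or 3 and 8 without wild-type MEK replicate 1.

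Genes of the maternal body axes changed singly. Among terminal patterning genes, 0 of 10 rose and tsl alone fell (log2 fold change -4.08, adjusted p = 0.0241) from 1.55 ± 0.433 CPM, a call lost in 5 of the 6 fits that leave out a library, while the receptor gene tor and the repressor gene cic were not called (log2 fold changes -0.23 and 0.28). That list had 2 rises with the gene length trend removed, 1 rise with upper-quartile factors, and 2 falls with an effective length offset or without MEK F53S replicate 2. Of 25 anterior and germ plasm factors, 3 rose and 5 fell, or 3 and 7 adjusted over the list alone. Besides bcd, gcl, spir, stau and hb fell, and the RNA-binding protein gene orb rose from 285 ± 96.4 to 737 ± 179 CPM (log2 fold change 1.37), with capu and exu (1.03 and 0.61). Of 17 dorsoventral factors, grk rose (0.71) and 4 fell, including Tl (-0.51) and sqd (-0.80), with equal counts adjusted over the list alone. The sqd call was lost with an effective length offset (log2 fold change -0.21, adjusted p = 0.198). None of these 3 lists was called by camera (adjusted p = 0.454, 0.191 and 0.278). The anterior list had 3 rises and 2 falls with limma on log2(TPM + 1), and 2 of each with an effective length offset. Its falls numbered 2 without MEK F53S replicate 1 or 3, 3 without wild-type MEK replicate 2 and 8 without MEK F53S replicate 2, and rises 1 without wild-type MEK replicate 2 or 3 or MEK F53S replicate 2. In the dorsoventral list, falls numbered 1 with limma, 2 with an effective length offset and 2 without any library except wild-type MEK replicate 1, and rises 2 without MEK F53S replicate 2.

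Regulators of egg activation and RNA decay had more falls than rises among their calls with edgeR, and for egg activation this depended on the method. Of 29 egg activation and early cell cycle genes, 3 rose and 11 fell, or 4 and 11 adjusted over the list alone. Those that fell included smg, the repressor of maternal RNA, from 6985 ± 569 to 4831 ± 221 CPM (log2 fold change -0.53), CycB (-0.41) and CycE (-0.64), and those that rose were png (1.02), fs(1)Ya (1.24) and trbl (0.97). Of 27 mRNA repression and decay factors, 2 rose (orb and Fmr1) and 7 fell, with the same counts adjusted over the list alone. The falls included gw, the GW182 protein gene (-0.81), and AGO2 (-0.89). Neither list was called (camera adjusted p = 0.159 and 0.183), and their falls numbered 4 each without MEK F53S replicate 3. The first list had 4 rises and 3 falls with limma on log2(TPM + 1), and 4 and 6 with an effective length offset. Its falls numbered 5 without wild-type MEK replicate 2 or 3 or MEK F53S replicate 1, and its rises 5 without wild-type MEK replicate 1. Rises of the second list numbered 4 without wild-type MEK replicate 1 and 1 without any other library. The second list had 4 rises and 8 falls with an effective length offset, and 2 rises and 4 falls with limma on log2(TPM + 1).

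Of 17 zygotic activators and chromatin genes, 0 rose and 7 fell, also adjusted over the list alone. The log2 fold changes of nej, Hcf, zld and Clamp were -0.82, -0.84, -0.80 and -0.79, and zld, which encodes the pioneer factor of the early genome, went from 498 ± 73.9 to 286 ± 23.6 CPM. The list ranked lower in MEK F53S (camera adjusted p = 0.00593), but not with an estimated correlation (adjusted p = 0.187 with an estimated correlation). Of 29 piRNA pathway genes, which silence transposons in the germline, 2 rose (papi and armi) and 8 fell, or 2 and 11 adjusted over the list alone. AGO3 fell from 1710 ± 50.9 to 853 ± 36.4 CPM (log2 fold change -1.002), and rhi, the HP1 family protein at piRNA clusters, from 107 ± 11.4 to 27.1 ± 5.81 CPM (-1.98). This list also ranked lower (camera adjusted p = 0.0134), and not so with an estimated correlation (adjusted p = 0.187 with an estimated correlation). Falls numbered 5 in the piRNA list without wild-type MEK replicate 2 or either of MEK F53S replicates 1 and 3, and rises 1 without wild-type MEK replicate 2 or 3 or MEK F53S replicate 2 or 3.

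**Figure D2:**
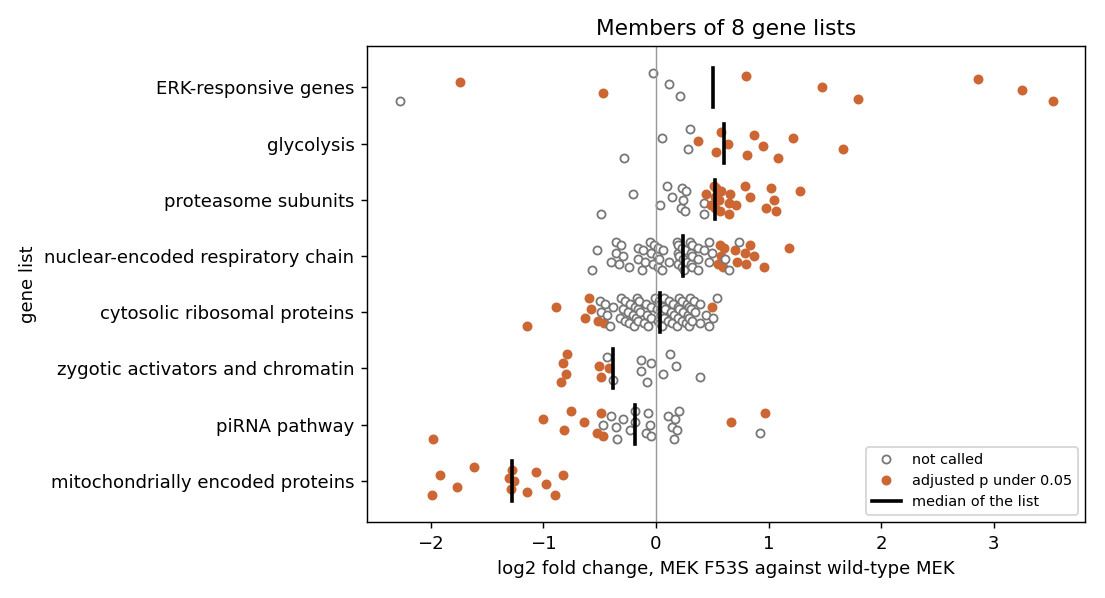
Log2 fold change of each tested member of 8 gene lists, MEK F53S against wild-type MEK, with called genes filled, other genes open and a bar at the median of each list. The glycolysis and proteasome lists have medians of 0.61 and 0.52, and all 13 mitochondrially encoded genes lie below 0.

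Many genes of glycolysis and of the proteasome rose. Of 14 glycolysis genes, 10 rose and 0 fell, also adjusted over the list alone. Pgi, at the second step of the pathway, rose from 135 ± 59.8 to 425 ± 65.1 CPM (log2 fold change 1.66), and Hex-A and Gapdh1 rose by 0.87 and 0.95. Of 32 proteasome subunit genes, 20 rose and 0 fell, or 22 and 1 adjusted over the list alone, among them Rpt1 (53.1 ± 3.3 to 108 ± 4.24 CPM) and Rpn10 (log2 fold change 1.28). Camera gave adjusted p = 0.000165 for glycolysis and 9.4e-06 for the proteasome. Neither held with an estimated correlation (adjusted p = 0.187 with an estimated correlation for both). With an effective length offset, 9 proteasome genes rose, and 8 glycolysis genes rose and 1 fell. Counts of rises also depended on single libraries: glycolysis had 4 without wild-type MEK replicate 2 or 3 and 6 without MEK F53S replicate 1 or 2, and the proteasome had 10 to 11 without any of wild-type MEK replicates 2 and 3 and MEK F53S replicates 1 and 3.

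All 13 mitochondrially encoded protein genes fell, also adjusted over the list alone, whereas nuclear genes for the respiratory chain did not. Called falls of the mitochondrial list numbered 10 with limma on log2(TPM + 1), 11 with an effective length offset and 12 without MEK F53S replicate 1. The mitochondrial share of counts was 8.73 ± 1.19% with wild-type MEK and 4.67 ± 0.553% with MEK F53S (exact permutation p = 0.1, the smallest possible). mt:CoI went from 24433 ± 3735 to 12446 ± 1448 CPM (log2 fold change -0.97) and mt:ND5 from 10065 ± 3148 to 2959 ± 238 CPM (-1.77). The list ranked lower (camera adjusted p = 2.43e-13), but not with an estimated correlation (adjusted p = 0.187 with an estimated correlation). Of 65 nuclear-encoded respiratory chain genes, 13 rose and 0 fell, or 9 and 0 adjusted over the list alone, with ND-51 (1.18) and UQCR-C1 (0.96) among them. That list was not called (adjusted p = 0.0808) except without MEK F53S replicate 2 (adjusted p = 0.00171). With the gene length trend removed 6 genes rose and 3 fell, and 2 to 3 genes rose without any of wild-type MEK replicates 2 and 3 and MEK F53S replicates 1 and 3. With an effective length offset 8 of these genes rose and 1 fell, with a replicate block 6 rose, and with limma on log2(TPM + 1) 18 rose. Without wild-type MEK replicate 1, 6 of its genes fell. Of 81 ribosomal protein genes, 1 rose and 7 fell, or 0 and 4 adjusted over the list alone, with RpS3A and RpLP1 at -0.51 and -1.15. The list was not called (adjusted p = 0.5), and its median of 0.03 and mean of -0.02 differ in sign. With limma on log2(TPM + 1), 7 rose and 1 fell, and with the gene length trend removed 2 rose and 16 fell. The list had 18 falls without wild-type MEK replicate 1, 18 rises without MEK F53S replicate 2, and 3 to 4 falls without any library other than wild-type MEK replicate 1. The 20 most abundant genes of each library took 14.4 ± 1.18% of counts with wild-type MEK and 10.3 ± 0.744% with MEK F53S.

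Structural eggshell, gut enzyme and accessory gland genes were nearly absent. Of 33 genes on the follicle cell and eggshell list, only br and Fs(2)Ket were tested. Fs(2)Ket, which is not a structural eggshell gene, had 908 CPM with wild-type MEK and 971 CPM with MEK F53S and was not called (log2 fold change 0.10). The 19 structural eggshell genes together had at most 22 counts in any library. None of 28 gut enzyme genes had enough counts to be tested, and the single accessory gland gene tested, Est-6, was not called. The immune genes Rel and PGRP-SD were not called either. Of 4 tested testis and sperm genes, mia rose (log2 fold change 1.87) from 2.10 ± 1.33 CPM, a call lost without wild-type MEK replicate 2 or MEK F53S replicate 2 or 3, and the list was not called (adjusted p = 0.741), with a median of -0.02 against an upward direction in camera. The yolk protein and fat body genes summed to between 357 and 514 CPM per library. Of 5 tested, apolpp, the lipophorin precursor, rose from 9.19 ± 1.21 to 78.6 ± 22.8 CPM (log2 fold change 3.10), Lsp1gamma rose to 1.27 CPM, and FASN1 fell by 1.39. Adjusted over the list alone, 3 rose and 1 fell, and without wild-type MEK replicate 1 there were 3 rises and 2 falls. Its camera adjusted p was 0.0418 (adjusted p = 0.187 with an estimated correlation), and the list was called in 0 of the 6 fits that leave out a library.

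Early zygotic transcripts were scarce in all libraries and uneven among those of MEK F53S. The 35 genes summed to between 15.04 and 16.5 CPM with wild-type MEK and to 26.2, 12.3 and 39.9 CPM in MEK F53S replicates 1, 2 and 3. Most of the wild-type MEK sum was Sry-alpha, at 14.3 CPM on average with wild-type MEK and 9.78 CPM with MEK F53S (log2 fold change -0.54, not called). Its exons are shared for 100% with Sry-beta on the same strand, so its value is uncertain. Of 5 genes of the list that were tested, 3 rose and 0 fell, also adjusted over the list alone. With a replicate block or limma on log2(TPM + 1) 1 rose, and with DESeq2 5 rose. Among the tested genes, sisA and Kr passed the count filter only through MEK F53S libraries, which favours rises. The sex determination gene sisA had 1 count with wild-type MEK and 277, 46 and 465 with MEK F53S. Kr had 5 counts with wild-type MEK and 163 with MEK F53S, and its call was lost in 5 of the 6 fits that leave out a library. In these fits, 1 to 2 genes rose, except for 5 without MEK F53S replicate 2, and 1 rose without MEK F53S replicate 3. The list was not called (camera adjusted p = 0.154), but was called higher with no filter (0.0367) and without wild-type MEK replicate 2 (0.0209), wild-type MEK replicate 3 (0.0186) or MEK F53S replicate 2 (0.00156). Without MEK F53S replicate 3, 5 ERK-responsive, 7 glycolysis and 11 proteasome genes were called higher. Among 18 heat shock and chaperone genes, 4 rose and 3 fell, or 6 and 4 adjusted over the list alone. Hsp26 and Hsp27 rose (log2 fold changes 1.51 and 0.99), Hsp22, whose exons lie within those of another gene, fell from 30.5 ± 3.86 to 6.34 ± 2.04 CPM, and single Hsp70 copies are uncertain because they share reads. The list was not called (adjusted p = 0.382), and its falls numbered 1 without wild-type MEK replicate 3 or MEK F53S replicate 3.

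Calls were denser on the small chromosome 4 than on the large chromosome arms. There, 39 of 73 tested genes were called, 53.4% against 24.7% on the other arms (Fisher's exact test, odds ratio 3.50, adjusted p = 1.06e-06 over 6 arms). Lower calls numbered 25, including fuss, gw and Hcf, and higher calls 14, including apolpp and pan (log2 fold change 1.04). Lower calls alone were 34.2% against 12.4% on the other arms (odds ratio 3.67, adjusted p = 8.79e-06), and higher calls alone 19.2% against 12.2% (odds ratio 1.7, adjusted p = 0.311). The difference between the directions was not tested. Fisher's exact test takes genes as independent, so its p-values do not measure spread between libraries or fly lines. The other arms had odds ratios between 0.925 and 1.08.

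**Figure D3:**
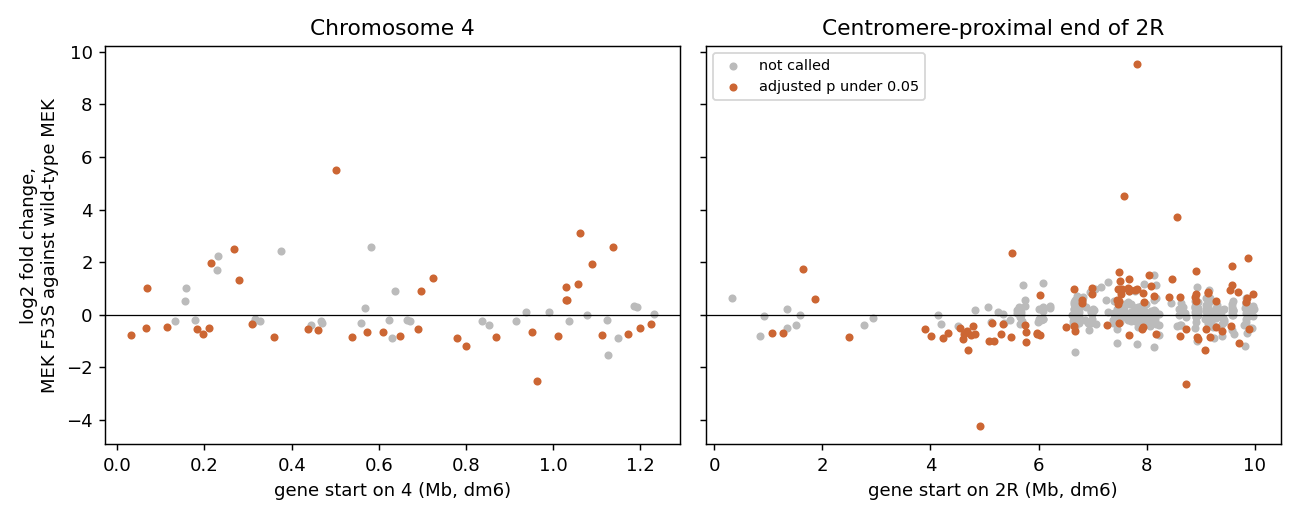
Log2 fold change of tested genes, MEK F53S against wild-type MEK, by gene start in Mb of dm6 on chromosome 4 and on the first 10 Mb of 2R, with called genes in orange. On chromosome 4, 25 called genes lie below 0 and 14 above, and between 4 and 5 Mb of 2R 12 of 16 genes were called lower.

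Libraries separated by group, and wild-type MEK replicate 1 lay apart within its group. The first principal component held 53.6% of the variance and split the groups, and correlations of log2 CPM across genes were 0.966 to 0.980 within groups and 0.933 to 0.946 between them. The second component held 17.2% of the variance and placed wild-type MEK replicate 1 at 42.4, against -15.8 and -21.5 for wild-type MEK replicates 2 and 3. Chi-square per degree of freedom between counts was 164 and 156 for that library against these, and 46.9 between them. In MEK F53S it was 134 and 118 for replicate 2 against the others, and 29.4 between those. Of the genes tested, 42.3% had all 3 libraries of a group above all of the other, where chance gives 10%. Genes with at least 10 counts numbered 7425 ± 57.0 with wild-type MEK and 7713 ± 144 with MEK F53S (exact permutation p = 0.1). With limma on log2(TPM + 1) the share of higher calls was 64.7%, against 48.9% with edgeR, and the median of all genes lay at 0.12 in place of 0.05. Fold changes also followed gene length and abundance. From the lowest to the highest of 10 groups of tested genes, the median log2 fold change went from 0.115 to -0.243 by length and from 0.221 to -0.288 by abundance. In a comparison chosen after seeing the data, each list was set against 10000 random sets matched on both. Of the 7 lists called, 5 had a median outside the middle 95% of the random sets. The piRNA list (-0.183, random sets -0.266 to 0.0969) and the yolk protein and fat body list (0.433, random sets -0.502 to 0.812) did not. Of the 12 not called, early zygotic genes (2.86, random sets -0.806 to 1.21) and the nuclear-encoded respiratory chain (0.24, random sets -0.021 to 0.217) lay above it. The early zygotic median rests on 5 genes, of which sisA and Kr passed the filter only through MEK F53S libraries. Matched random sets do not correct for this, and they measure spread between genes, not between libraries. The number of calls was 2614 without wild-type MEK replicate 1, and it was 1016, 1116, 1075 and 1001 without wild-type MEK replicate 2 or 3 or MEK F53S replicate 1 or 3.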

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

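The alternatives without mitochondrially encoded genes and with a gene length trend removed were chosen after seeing the data, and the others before. Across the settings that keep all libraries, 0 genes called by edgeR were called in the opposite direction. Genes higher in MEK F53S numbered 930 and ranged from 424 to 1304 when 1 library was left out, and 382 were at least 2-fold. Genes lower numbered 970 and ranged from 506 to 1310 on leaving out 1 library; 157 were at least 2-fold, and limma on log2(TPM + 1) called 572. Leaving out wild-type MEK replicate 1 raised the calls to 2614, and leaving out wild-type MEK replicate 2 or 3 or MEK F53S replicate 1 or 3 lowered them to 1016, 1116, 1075 and 1001; fewer samples weaken each test, and the cause of the rise was not tested. Of 7 gene lists called, 0 were called with an estimated correlation between genes, and 6 kept their call on leaving out each library, all but the yolk protein and fat body list. The test fry, which asks whether a list changed without comparing it with other genes, called 8, the 7 and the background and transgene markers (fry adjusted p = 0.0274, camera adjusted p = 0.373). Lists not called also gained calls: early zygotic genes in 3 of the 6 fits that leave out a library and with no filter, and the anterior, mRNA decay, ribosomal and respiratory chain lists in 1 such fit each. The follicle cell and eggshell list, with 2 genes past the filter, was called only without wild-type MEK replicate 2 or MEK F53S replicate 1 (adjusted p = 0.00947 and 4.44e-05), where 3 were tested, and not with no filter, where 16 were (adjusted p = 0.331). The odds ratio of calls on chromosome 4 was 1.7 for higher calls alone, 3.67 for lower calls, 3.24 with DESeq2 and 3.79 with the gene length trend removed. The log2 fold change of Dsor1 stayed near 0, from -0.186 to 0.0381 on leaving out 1 library, 0.017 with upper-quartile factors and 0.0069 with limma, and it was called in no setting. Values of the 35 genes named by size, by p, or as Dsor1 and background markers numbered 627. Of these, 617 kept their direction and their side of the threshold, and 0 reversed with a call in either fit. Another 6 changed sign without a call, and the 4 calls lost were all of His2B:CG33882. Of 1246 values of 70 named list members, 57 calls were lost, mostly of tsl, gd, Kr, rho, UQCR-C2 and ND-B14.5A. Among the same values, 0 reversed with a call in either fit and 13 changed sign without a call. Replicate numbers did not pair the samples, since deviations of same-numbered libraries correlated at -0.0582, -0.121 and 0.113. With the number as a replicate block, 744 genes were higher and 742 lower, and Dsor1 had a log2 fold change of -0.04. Depth was not varied. Of 35 early zygotic genes, 5 passed the filter and 24 were tested with no filter, and the libraries had 226 to 659 genes with 1 to 9 counts.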

Other observations

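The tests on marker totals, centromere-proximal genes, random gene sets, transcript lengths and companions of bcd were chosen after the results had been seen. Several genes outside the naming rule were picked by hand, also after their values were seen. The repressor gene brk went from 4 counts in all wild-type MEK libraries to 1422 with MEK F53S (log2 fold change 8.02 ± 0.49 SE, adjusted p = 1.65e-05). Eip75B and Eip74EF rose by 1.05 and 2.54, the ecdysone receptor gene EcR was not called (-0.17, adjusted p = 0.303), and no list of ecdysone-induced genes was tested. With a mean of at least 3 CPM, 7 genes had counts only in MEK F53S libraries and 2 only in wild-type MEK libraries. Of these, His2B:CG17949, pre-mod(mdg4)-O and Hsp70Aa had nearly all their counts in 1 library each and were not tested, and the other 5 and 1 were called. Nepl19 (3R, 28878024 to 28880122) and its neighbour Nepl20 (3R, 28880792 to 28882945) were both read only with MEK F53S, at 17.7 ± 3.63 and 3.40 ± 1.01 CPM, as was Syt4 at 5.11 ± 1.16 CPM. The reverse held for inaF-D (X, 11724668 to 11729099), with 232, 216 and 215 counts in the wild-type MEK libraries and 0 in each MEK F53S library, at least 90.6-fold lower, but 84.1% of its exon length is shared with inaF-B and its reads cannot be assigned with certainty. At the same locus, inaF-A went from 5.36 ± 0.777 to 0.101 ± 0.0966 CPM (adjusted p = 0.000472).

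The deposited length of a gene differs between libraries, as it would if transcripts were weighted by abundance, and was compared with limma on log2 length over 3629 genes with at least 100 counts in every library and a length that varied. Of these, 13 differed between the groups, 4 longer and 9 shorter with MEK F53S. CG5455 went from 2802 ± 46.3 to 1445 ± 0 bases while its level rose by 1.78 on the log2 scale. Oseg1 went from 4669 ± 85.5 to 2757 ± 178 bases and Epg5 from 4624 ± 107 to 7578 ± 32.3 bases, neither with a called change in level (log2 fold changes -0.33 and 0.22). On simulated lengths the test recovered 66% of 200 genes changed 1.3-fold, with 7 false among 139 calls.

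The rise of ERK-responsive genes in MEK F53S eggs was set against RNA from other cells. The 6 genes that rose gained 327 CPM in total, whereas 19 structural eggshell genes, of which 0 to 3 had any count in a library, changed by 0.0512 ± 0.148 CPM (SE), which argues against follicle cells making the eggshell. Follicle cells at other stages stay open. The called gene of the follicle cell list, br, gained 79 ± 19 CPM (SE), more than 10% of 327 CPM. It was taken because it was called and is also ecdysone-induced, so its rise is no evidence for or against RNA from such cells. Zygotic transcription in fertilised embryos was tested on 35 early zygotic genes, rho included, which gained 10.2 ± 7.99 CPM (SE), under 10% of 327 CPM by more than 2 SE. Within this total Sry-alpha, whose exons are shared with Sry-beta, fell from 14.3 to 9.78 CPM. The other genes therefore gained more, and the bound was not checked without Sry-alpha. Zygotic transcription stays open for sisA, Kr and rho, whose counts were highest in MEK F53S replicate 3. More transcription of pnt, aos, Mkp3, spi and kay in the female germline was not tested, since only RNA levels of eggs were measured.

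Genes on chromosome 4 and next to the centromeres of the large arms were called lower in MEK F53S more often than other genes. Among the 50 tested genes nearest the centromere on each of 5 arms, 23 of 250 were called higher and 73 lower (29.2%, against 11.8% elsewhere on these arms), and the lower ones include rl and lt, long known as heterochromatic genes, and AGO3, Clamp and Nipped-A. On 2L, 17 of the 50 were histone copies that share reads and held 6 of its 9 higher calls, and the other 33 had 3 higher and 15 lower calls. Against 10000 random sets matched on gene length and abundance, the median log2 fold change of chromosome 4 was -0.245 (-0.187 to 0.0901 for the middle of the random sets, 0.002 of them as low) and that of the centromere-proximal genes -0.17 (-0.0726 to 0.0661, 1e-04 as low, the smallest these draws can give), so neither trend accounts for the whole difference in these libraries. Both shares measure spread between genes drawn as if independent. They do not measure spread between libraries or fly lines. A sequence difference between the fly lines and a change in heterochromatin may both be considered, with the gene of the heterochromatin protein HP1a at a log2 fold change of -0.52 (adjusted p = 0.0378), and neither was tested.

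The fall of bcd was compared with that of transcripts that gain poly(A) at egg activation or are cleared after it. Tl, tor and hb, which gain poly(A) at egg activation as bcd does, had a mean log2 fold change of -0.44 ± 0.07 SE against -1.81 ± 0.12 for bcd. The SE of such means treats the genes as independent, although they come from the same 6 libraries, so it is likely too small. A lower capture equal for all these transcripts would not account for the whole fall of bcd. Whether RNA was selected by poly(A) is not given, and an unequal effect was not tested. Hsp83, stg and pgc, which are cleared from activated eggs, had a mean of -0.18 ± 0.08 SE. Whether their clearance had begun by the time of collection was not measured, so these genes cannot decide whether more decay lowered bcd. More decay after activation therefore stays open. A lower supply of bcd RNA from the ovary, or a difference in bcd between the fly lines, also stays open as a hypothesis and was not tested.

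Of the 10 splits of the 6 samples into 3 and 3, only 1, the real one, gave as many as 1900 called genes, and the highest of the others gave 1. With 10 splits no share under 0.05 can be reached.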
